A study of Rattus norvegicus with 24 samples.

How the data were processed

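The deposited scanner files held 1 spot on each line, with the mean signal and median background of both dyes as intensity per the file headers (linear, not logged) and a log10 log ratio of the scanner software per the file headers. The series table held a log2 ratio of treated over vehicle per the labels. The signals had been read with Agilent Feature Extraction 9.1.3.1. RNA had been isolated with RNeasy kits, amplified and labelled as cRNA, per the labels. Channel 1 (Cy5) held a pool of vehicle RNA and channel 2 (Cy3) the RNA of 1 treated rat on each of 24 arrays, and no array had the dyes swapped. The labels describe a pool of 4 control rats, which counts as 1 sample, and its spread is left out of every test against vehicle. Given in water, tetracycline hydrochloride shared no pool with the corn oil compounds, and whether those shared one is not given. Where pools differed, their spread is also left out of every contrast between compounds and classes. The tests then have an error too small by an unknown amount.

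Signals were background corrected with normexp (offset 50) in limma and scaled with loess within each array, with the weight of control spots set to 0. Control spots and spots that the scanner software marked as outliers were then left out, which took between 0 and 74 outlier spots per array. The 2 copies of each probe were averaged, and the sign was turned so that each log2 ratio is treated over vehicle. Of 21890 probes on the arrays, 16085 were kept because they lay well above background in 1 channel on all 4 arrays of at least 1 compound. A gene was represented by its brightest probe, and 3675 of the 11494 genes had several kept probes. Gene names came from the array design, updated through a RefSeq gene table of the rat assembly GRCr8 that was used for names alone: 6195 probes matched a current symbol, 1915 an older symbol, 901 a RefSeq record and 621 a gene ID, 96 kept the name of the array design and 12162 had no gene name. No genomic positions were used.

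All 24 arrays were fitted together with limma lmFit and eBayes, with 1 mean for each compound (18 residual degrees of freedom, 2.92 prior degrees of freedom). The contrasts were each compound against vehicle, each compound against the mean of the other 5, hexachloroethane against 1,2,3-trichloropropane, and 4 carcinogens against 2 non-carcinogens with compound as a random block (duplicateCorrelation, consensus correlation 0.58). Genes were called at a Benjamini-Hochberg adjusted p under 0.05 within the comparison and at least 2-fold. Replicate numbers were not used to pair rats. Each compound lay on 1 of 6 slides of its own, so slide and compound cannot be told apart. The arrays were scanned on 4 days, hexachloroethane with tetracycline hydrochloride on day 1 and monuron with 1,2-dichlorobenzene on day 4.

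Choices on the fits, the limits, the lists and the alternatives were made before the data were examined, apart from those named as later. The rule for named genes took, per compound, the 10 largest increases and the 10 largest decreases among genes called against vehicle, changed the same way on all 4 arrays, and past an adjusted p of 0.05 in the same direction against the mean of the other 5 compounds, leaving out genes without a symbol and provisional names. From each gene list with a called member, up to 4 called members with the largest change could be named. For hexachloroethane against 1,2,3-trichloropropane the rule took the 5 largest called genes with a symbol in each direction, and the comparison of the classes had no called gene to name. A compound whose genes passed the rule fewer than 10 times in a direction has fewer names, as tetracycline hydrochloride does with 4 increases and 3 decreases. Genes named for being called under 5 or 6 compounds were chosen after their values were seen. Where the vehicle channel of a gene was not well above background, the change is given as a lower limit.

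The 26 gene lists covered targets of the aryl hydrocarbon receptor, CAR and PXR, Nrf2, p53 and PPARalpha, pathways of cholesterol, fatty acid and bile acid metabolism, oxidative phosphorylation, the cell cycle, ER stress, the acute phase response and interferon, genes biased by sex or liver zone, secreted proteins, and markers of other cell types, including neutrophils and pancreatic acinar cells. They were tested with limma camera at a preset correlation of 0.01 per compound against vehicle, adjusted over all 144 tests of the 24 lists with at least 5 measured members. Means and medians of the members, and the mean and the test, had the same sign in all 54 called tests. With a correlation between genes estimated from the data 0 tests were called against vehicle and 0 against the other 5 compounds (smallest adjusted p = 0.121 there), while fry, another limma test, called 87 of 144 against vehicle. Members called were counted with p adjusted over all genes and over the list alone, and the 2 counts were equal for every list and compound.

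The fits were first tried on log ratios simulated with the spread of each gene in the arrays and known changes. Against vehicle they recovered 2 of 65 genes changed 1.5-fold, 44 of 77 changed 2-fold and 58 of 58 changed 4-fold, with 1 false call. Against the other 5 compounds they recovered 0 of 65, 42 of 77 and 58 of 58, with 0 false calls in limma. Of 3 lists shifted by 0.3 log2, camera recovered 2 with 0 false calls. Correlation between genes was not simulated, so this does not vouch for the list calls.

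The series table had 21960 lines, of which 21890 matched a probe and 70 were not used here, with 0 of its sample columns left unused. Its log2 ratios served as an alternative to the scaling used here. Spiked control transcripts (10 probes) shifted by between -0.39 and 0.57 log2 as a set in the means of the compounds and were not used for the scaling. Versions were R 4.3.3, limma 3.58.1, statmod 1.5.0, data.table (1.17.8), python 3.11.15 and matplotlib 3.10.9.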

Results

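Liver gene expression was measured in 24 male F344 rats, an inbred laboratory strain, after 28 days of daily gavage with 1 of 6 compounds. The design names 4 of the compounds carcinogens: hexachloroethane at 500 mg/kg/day, 1,2,3-trichloropropane at 50 mg/kg/day, 1-amino-2-methylanthraquinone at 150 mg/kg/day and 3-(4-chlorophenyl)-1,1-dimethylurea, a herbicide with the common name monuron, at 250 mg/kg/day. It names 2 non-carcinogens, 1,2-dichlorobenzene at 300 mg/kg/day and tetracycline hydrochloride, an antibiotic, at 1000 mg/kg/day. Each compound was given to 4 rats, 5 weeks old per the labels, tetracycline hydrochloride in water and the other compounds in corn oil, at 5 ml per kg. The liver RNA of each treated rat, labelled with Cy3, was hybridised to 1 Agilent array with Cy5-labelled RNA pooled from vehicle-treated rats. The dye ratio thus gave the change in 1 treated rat against vehicle, with the same dye for treated RNA on all 24 arrays.

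Between 59.8 and 71.8% of the probes lay well above background in the treated channel and between 64.2 and 75.9% in the vehicle channel. The median signal per array ran from 412 to 494 in the treated channel and from 590 to 691 in the vehicle channel. After the dimmest probes were left out, 11494 genes were tested, 4740 of them with a gene symbol. The number of arrays limits the precision. Values below are mean log2 ratios of treated over vehicle ± SD over the 4 rats of a compound (n = 4), unless another quantity is named.

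The question for each compound was which liver genes differed from vehicle, and which differed from the mean of the other 5 compounds. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and a change of at least 2-fold in limma. Against vehicle, 1-amino-2-methylanthraquinone changed 245 genes and tetracycline hydrochloride 33, with the other 4 compounds between 105 and 183. A dye effect that is alike on all arrays stays in each of these ratios, while it cancels in the contrast with the other 5 compounds. Corn oil compounds may have shared a vehicle pool, tetracycline hydrochloride did not, and a difference between pools stays in both contrasts. That contrast called 149 genes for 1-amino-2-methylanthraquinone and between 47 and 73 for each other compound.

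**Figure D1:**
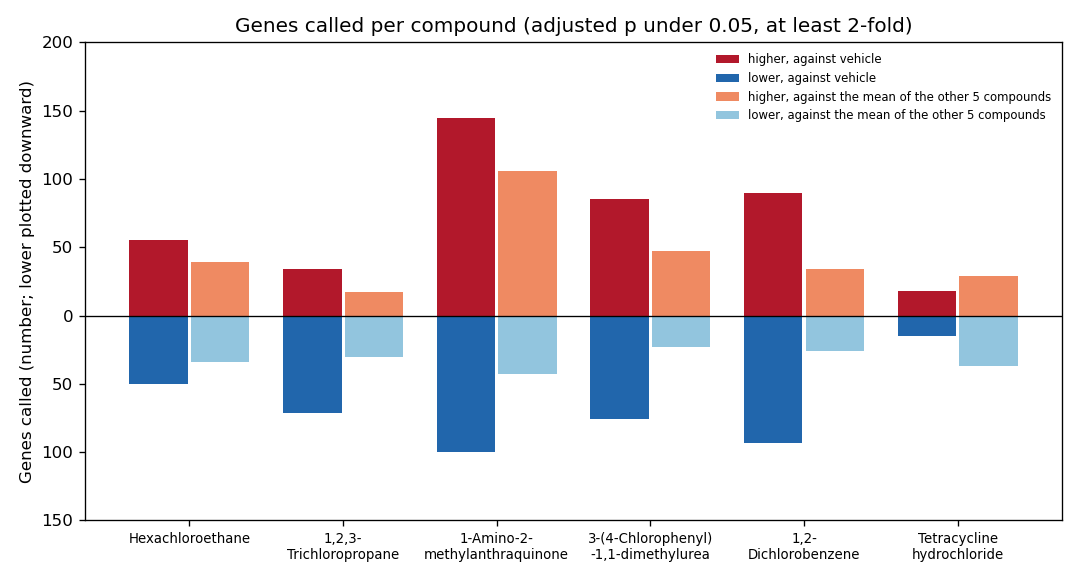
Number of genes called higher and lower (vertical axis) for each of the 6 compounds, against vehicle and against the mean of the other 5 compounds. 1-Amino-2-methylanthraquinone had the tallest bars, with 145 genes higher and 100 lower against vehicle, and tetracycline hydrochloride the shortest against vehicle, with 18 and 15.

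Hexachloroethane, a chlorinated alkane, raised Grin2c most and lowered Car3 most among the named genes. The carboxylesterases Ces2c (2.65 ± 0.33) and Ces2 (2.30 ± 0.33), the glucuronosyltransferase Ugt2b1 (2.43 ± 0.14) and the cytochromes P450 Cyp2c37 (2.12 ± 0.14), Cyp2c6v1 (2.08 ± 0.15) and Cyp2b15 (2.05 ± 0.13) rose. Gpx2, a glutathione peroxidase, rose by 2.30 ± 0.36, Asns, the asparagine synthetase, by 1.58 ± 0.71, and the annexin gene Anxa7 by 1.43 ± 0.26. Grin2c encodes a subunit of the NMDA glutamate receptor (3.81 ± 0.53). Car3 encodes a carbonic anhydrase abundant in liver and muscle (-2.92 ± 0.14). Other decreases were in Gadd45g, a growth arrest gene (-2.19 ± 0.68), Serpina7, which encodes thyroxine-binding globulin (-1.87 ± 0.73), Spdye4c (-1.86 ± 0.84), the membrane peptidase gene Mme (-1.68 ± 0.66), the chemokine gene Cxcl14 (-1.46 ± 0.51), Pbsn (-1.44 ± 0.75) and the alcohol dehydrogenase Adh1c (-1.34 ± 0.27). Glul, the glutamine synthetase of hepatocytes around the central vein, fell (-1.21 ± 0.21), and so did the glutamate transporter gene Slc1a2 (-1.20 ± 0.19). All 20 of these genes moved in the same direction against tetracycline hydrochloride, which was scanned on the same day, and all passed an adjusted p under 0.05 there. The same arrays had chosen the genes, here and in the comparisons within a day for monuron, 1,2-dichlorobenzene and tetracycline hydrochloride, so these counts say little about scan day.

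Hexachloroethane changed 105 genes against vehicle, 55 higher and 50 lower, and 67 of them also passed against the mean of the other 5 compounds. That contrast called 73 genes, 39 higher and 34 lower. For Cyp2c37, 2 of 4 other probes lay below 0. Whether Cyp2c37 and Cyp2c6v1, or Ces2 and Ces2c, gave separate signals was not tested. The split moved with the scaling. Median centring in place of loess called 24 higher and 625 lower. The scanner's log ratio called 113 and 180 against vehicle and 80 and 107 against the other 5.

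Gene lists fixed before the data were examined were tested with camera, a limma test that compares a list with all other genes, and the numbers of members called were the same when p was adjusted over the list alone. Under hexachloroethane the targets of the nuclear receptors CAR and PXR rose as a list (mean 0.77 ± 0.11, adjusted p = 1.50e-06, adjusted p = 0.190 with an estimated correlation): 13 of 18 measured members were not called and 5 rose, among them Ces2 and Ugt2b1. Targets of the oxidative stress factor Nrf2 rose (mean 0.61 ± 0.038, adjusted p = 1.47e-08, adjusted p = 0.190 with an estimated correlation), and 20 of 26 measured members were not called and 6 rose, among them the glutathione transferase Gsta3 (2.38 ± 0.13), the transporter Abcc3 (1.32 ± 0.34), the quinone reductase Nqo1 (1.20 ± 0.16) and malic enzyme Me1 (1.27 ± 0.33). Cyp1a1, a target of the aryl hydrocarbon receptor, rose by 2.75 ± 1.20, while the list of that receptor's targets was not called (mean 0.58 ± 0.17, adjusted p = 0.0903). Genes of cholesterol synthesis rose by a small amount (mean 0.35 ± 0.10, adjusted p = 0.000544, adjusted p = 0.604 with an estimated correlation), and no member of 19 measured was called at 2-fold, with 11 higher and 0 lower at the adjusted p alone. Nuclear-encoded genes of oxidative phosphorylation rose by less (mean 0.087 ± 0.058, adjusted p = 0.00206, adjusted p = 0.604 with an estimated correlation), and no member of 29 measured was called at 2-fold, with 14 higher and 2 lower at the adjusted p alone. Male-biased liver genes fell (mean -0.52 ± 0.087, adjusted p = 0.00687, adjusted p = 0.323 with an estimated correlation), and 11 of 14 measured members were not called and 3 fell, Car3 and the dehydrogenase Dhrs7 (-1.59 ± 0.41) among them. Periportal hepatocyte genes fell (mean -0.38 ± 0.22, adjusted p = 0.00206, adjusted p = 0.323 with an estimated correlation), and 17 of 18 measured members were not called and 1 fell, the serine dehydratase Sds (-1.31 ± 0.44). Hepatocyte secreted proteins fell (mean -0.45 ± 0.019, adjusted p = 1.55e-07, adjusted p = 0.234 with an estimated correlation), and 19 of 20 measured members were not called and 1 fell, the apolipoprotein Apoc3 (-1.15 ± 0.18). The acute phase response also fell (mean -0.30 ± 0.052, adjusted p = 0.00112, adjusted p = 0.25 with an estimated correlation), and no member of 24 measured was called at 2-fold, with 0 higher and 12 lower at the adjusted p alone. Oat, an ornithine aminotransferase of perivenous hepatocytes, fell (-2.21 ± 0.62), while its list was not called (mean -0.30 ± 0.11, adjusted p = 0.334).

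Of the 6 tested lists of other cell types, 4 were not called under hexachloroethane. Kupffer cells and macrophages (mean -0.17 ± 0.38, adjusted p = 0.368), liver endothelium (mean -0.13 ± 0.19, adjusted p = 0.436), bile duct cells (mean 0.16 ± 0.11, adjusted p = 0.296) and red blood cell precursors (mean -0.043 ± 0.18, adjusted p = 0.856) were those. Genes of stellate cells and fibrosis fell (mean -0.19 ± 0.16, adjusted p = 0.0402, adjusted p = 0.641 with an estimated correlation), and no member of 20 measured was called at 2-fold, with 0 higher and 10 lower at the adjusted p alone. That call ended without replicate 1 or 3 (-0.13 and -0.16, adjusted p 0.267 and 0.0851). Lymphocyte genes fell (mean -0.21 ± 0.16, adjusted p = 0.0226, adjusted p = 0.641 with an estimated correlation), and no member of 12 measured was called at 2-fold, with 0 higher and 7 lower at the adjusted p alone. Their call ended without replicate 1 or 4 (both -0.17, adjusted p 0.114 and 0.0651). With median centring in place of loess the calls for CAR and PXR targets, Nrf2 targets, stellate cells and lymphocytes ended and the means of Nrf2 targets, cholesterol synthesis and oxidative phosphorylation turned negative. Lists were tested against the mean of the other 5 compounds too, which was chosen after the data were examined. There the CAR and PXR targets and the acute phase response kept their call, and the other 8 lists did not. Those 2 calls were lost there too with an estimated correlation (adjusted p 0.192 and 0.650).

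1,2,3-Trichloropropane, a 3-carbon chlorinated alkane, raised the glutathione transferase Gsta3 and lowered Inmt and the ornithine aminotransferase Oat most among the named genes. Gsta3 rose by 4.58 ± 0.49, Gstt3 by 2.31 ± 0.27 and Gstp1, a placental form often raised in liver foci, by 2.14 ± 0.59. Akr7a3, an aflatoxin aldehyde reductase, rose by 2.60 ± 0.44, the aldehyde dehydrogenase Aldh1a4 by 2.20 ± 0.25, and Ugt2b7 by 2.04 ± 0.49. Increases were also seen in the metal-binding protein gene Mt1 (1.99 ± 0.75), the serine synthesis gene Phgdh (1.98 ± 0.41), the chemokine gene Cxcl1 (1.65 ± 1.16) and the liver hormone gene Fgf21 (1.5 ± 0.38). The methyltransferase Inmt (-2.77 ± 0.72), Oat (-2.60 ± 0.32), Sds (-2.41 ± 0.25), the tyrosine aminotransferase Tat (-2.21 ± 1.26) and the aspartate aminotransferase Got1 (-1.57 ± 0.34) fell. Noct, a gene with a daily rhythm in liver (-2.34 ± 1.46), the taurine transporter Slc6a6 (-1.76 ± 0.35), the sterol sensor Insig1 (-1.69 ± 1.35), the growth factor binding protein Igfbp1 (-1.69 ± 0.14) and the secreted protein gene Tsku (-1.64 ± 1.54) fell as well.

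1,2,3-Trichloropropane changed 105 genes against vehicle, 34 higher and 71 lower, and 61 of them also passed against the other 5 compounds. That contrast called 47 genes, 17 higher and 30 lower. Median centring in place of loess called 37 genes higher and 404 lower against vehicle. No other compound was scanned on the day of these arrays, so day and compound cannot be told apart.

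None of the 6 tested lists of other cell types was called under 1,2,3-trichloropropane. Stellate cells and fibrosis (mean -0.15 ± 0.039, adjusted p = 0.0519) had 1 member higher and 7 lower at the adjusted p alone, Kupffer cells and macrophages (mean -0.24 ± 0.19, adjusted p = 0.0578) 0 higher and 5 lower, and bile duct cells (mean 0.12 ± 0.10, adjusted p = 0.229) 4 higher and 0 lower. The other list means were -0.10 ± 0.12 for liver endothelium, 0.020 ± 0.13 for lymphocytes and 0.083 ± 0.18 for red blood cell precursors. As a list, Nrf2 targets rose (mean 0.69 ± 0.053, adjusted p = 5.67e-05, adjusted p = 0.323 with an estimated correlation), and 20 of 26 measured members were not called and 6 rose, among them Gsta3, Akr7a3 and Aldh1a1 (2.38 ± 0.24). Genes of the cell cycle rose (mean 0.30 ± 0.27, adjusted p = 0.00665, adjusted p = 0.675 with an estimated correlation), and 22 of 23 measured members were not called and 1 rose, the replication licensing gene Mcm3 (1.03 ± 0.14), which was under 2-fold without replicate 2 (0.97). Periportal genes fell (mean -0.65 ± 0.15, adjusted p = 0.00331, adjusted p = 0.323 with an estimated correlation), and 13 of 18 measured members were not called and 5 fell, including Sds, Tat and the gluconeogenic enzymes Pck1 (-1.73 ± 0.66) and G6pc1 (-1.21 ± 0.20). Perivenous genes fell (mean -0.42 ± 0.12, adjusted p = 0.0447, adjusted p = 0.384 with an estimated correlation), and 14 of 15 measured members were not called and 1 fell, which was Oat. Their median was -0.18. Hepatocyte secreted proteins fell (mean -0.41 ± 0.070, adjusted p = 4.10e-07, adjusted p = 0.234 with an estimated correlation), and 19 of 20 measured members were not called and 1 fell, the protease inhibitor Serpina1 (-1.06 ± 0.11). In the acute phase response, which fell as a list (mean -0.17 ± 0.078, adjusted p = 0.0159, adjusted p = 0.413 with an estimated correlation), 1 rose, 1 fell and 22 of 24 measured members were not called: Cxcl1 was higher and the haemoglobin-binding protein gene Hp lower (-1.05 ± 0.15). Oxidative phosphorylation rose slightly (mean 0.063 ± 0.032, adjusted p = 0.0299, adjusted p = 0.656 with an estimated correlation), and no member of 29 measured was called at 2-fold, with 14 higher and 4 lower at the adjusted p alone. CAR and PXR targets were not called (mean 0.0085 ± 0.12, adjusted p = 0.369), although Ugt2b1 rose (1.29 ± 0.092) and Cyp3a9 fell (-2.08 ± 0.39). Members of other lists that changed were the amino acid response gene Asns (1.3 ± 0.53), the sulfotransferase Sult1e1 (-1.44 ± 0.32), the phosphatidate phosphatase Lpin1 (-1.36 ± 1.06) and the bile acid ligase Slc27a5 (-1.22 ± 0.29). Without replicate 3 the calls for perivenous genes (-0.38, adjusted p = 0.0649) and for oxidative phosphorylation (0.048, adjusted p = 0.0660) ended. None of these 7 lists kept its call against the mean of the other 5 compounds. Called there and not against vehicle were cholesterol synthesis (mean -0.46, adjusted p = 0.000355), CAR and PXR targets (mean -0.27, adjusted p = 0.0115), aryl hydrocarbon receptor targets (mean -0.52, adjusted p = 0.0247) and Kupffer genes (mean -0.21, adjusted p = 0.0462), which were lower, and male-biased genes (mean 0.41, adjusted p = 0.00457) and lymphocytes (mean 0.18, adjusted p = 0.0265), which were higher. All 6 were lost with an estimated correlation (adjusted p 0.199 to 0.857). Median centring ended the calls for Nrf2 targets, cell cycle and acute phase response and turned oxidative phosphorylation negative.

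Hexachloroethane and 1,2,3-trichloropropane are both short chlorinated alkanes given in corn oil, with 2 carbons and 6 chlorines against 3 carbons and 3 chlorines. Their doses differed, 500 against 50 mg/kg/day, so structure and dose cannot be told apart, and neither can slide or scan day. The difference between them was called for 160 genes, 93 higher under hexachloroethane and 67 lower. The split was 84 and 84 with median centring, 189 and 194 with the scanner's log ratio and 191 and 197 with the series table. Noct was 3.39 log2 higher under hexachloroethane (SE 0.72, adjusted p = 0.00113), Grin2c 3.19 (SE 0.23), Tsku 3.02 (SE 0.50), the zinc finger gene Zfp354a 2.96 (SE 0.66) and Ces2c 2.40 (SE 0.17). Lower under hexachloroethane were Mt1 (-2.87, SE 0.37), Gadd45g (-2.72, SE 0.55), Car3 (-2.45, SE 0.28), Gstp1 (-2.42, SE 0.20) and Serpina7 (-2.29, SE 0.51). CAR and PXR targets were higher under hexachloroethane (mean difference 0.77, adjusted p = 5.30e-05, adjusted p = 0.386 with an estimated correlation), and so was cholesterol synthesis (mean difference 0.54, adjusted p = 0.00362, adjusted p = 0.981 with an estimated correlation).

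The 2 chlorinated alkanes changed 22 genes in the same direction against vehicle, 13 higher and 9 lower, where 0.163 and 0.309 would be met by chance, and 3 genes in opposite directions. The chance values assume separate controls. A vehicle pool shared by both, or a dye effect alike on all arrays, would add to this overlap. Of the 22 genes, 6 differed between the compounds, among them Gsta3 (-2.20, 95% interval -3.02 to -1.38) and Gpx2 (1.18, 95% interval 0.81 to 1.55). For 4 of the 22 the 95% interval of the difference lay within 1 log2 unit of 0, for instance Nqo1 (0.17, -0.11 to 0.45) and Asns (0.27, -0.31 to 0.86). Oat fell under both, with a difference of 0.39 and an interval from -0.43 to 1.22. Over all genes, 11003 of 11494 (95.7%) had an interval within 1 log2 unit of 0.

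1-Amino-2-methylanthraquinone, an aromatic amine with a flat ring system, raised Cyp1a1 most and lowered Cyp3a9 most among the named genes. Cyp1a1 rose by 5.01 ± 0.44 and Cyp1a2 by 2.46 ± 0.18, both cytochromes P450 that activate aromatic amines and hydrocarbons. The tight junction gene Cldn7 rose by 3.39 ± 0.76 and the membrane serine protease gene Prss8 by 2.70 ± 0.34. Grin2c (3.34 ± 0.23), Samd7 (2.84 ± 0.45), Gpx2 (2.78 ± 0.28), the efflux pump Abcb1 (2.54 ± 0.49), Aldh1a1 (2.46 ± 0.24) and the acyl-CoA synthetase Acsm5 (2.36 ± 0.40) also rose. Cyp3a9 fell by the most (-3.91 ± 0.51), followed by the apolipoprotein Apoa4 (-3.24 ± 0.87), Dhrs7 (-2.55 ± 0.56), Prss32 (-2.5 ± 0.34) and Car3 (-2.49 ± 0.87). Tsnaxip1 (-2.31 ± 0.84), the chromatin protein gene Hmga1 (-1.88 ± 0.92), Apoa2 (-1.85 ± 0.45), the peroxisomal oxidase Hao2 (-1.85 ± 0.46) and the peroxisomal lyase Hacl1 (-1.85 ± 0.80) fell too. The other probe of Dhrs7 and 1 of 2 other probes of Hmga1 lay on the other side of 0.

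1-Amino-2-methylanthraquinone changed 245 genes against vehicle, 145 higher and 100 lower, and 199 of them also passed against the other 5 compounds, where 149 were called at 2-fold, 106 higher and 43 lower. Median centring in place of loess called 114 genes higher and 968 lower against vehicle, and 71 and 64 against the other 5 compounds. No other compound shared the scan day, so the 2 cannot be told apart.

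Bile duct genes rose as a list under 1-amino-2-methylanthraquinone (mean 1.28 ± 0.26, adjusted p = 1.48e-07, adjusted p = 0.190 with an estimated correlation), and 5 of 14 measured members were not called and 9 rose. Examples besides Cldn7 were the adhesion molecule Epcam (2.11 ± 0.27), the secretin receptor Sctr (1.76 ± 0.78) and osteopontin, Spp1 (1.72 ± 0.20). Markers of other liver cells were not called against vehicle: the means were 0.22 ± 0.080 for stellate cells and fibrosis, 0.18 ± 0.14 for Kupffer cells and macrophages, 0.044 ± 0.053 for liver endothelium and -0.094 ± 0.12 for lymphocytes. Genes of stellate cells and fibrosis had 10 members higher and 2 lower at the adjusted p alone. That list was called against the mean of the other 5 compounds (mean 0.40, adjusted p = 0.000202, adjusted p = 0.451 with an estimated correlation). Aryl hydrocarbon receptor targets rose (mean 1.32 ± 0.14, adjusted p = 0.00206, adjusted p = 0.190 with an estimated correlation), and 5 of 8 measured members were not called and 3 rose, which were Cyp1a1, Cyp1a2 and Nqo1 (1.76 ± 0.17). Nrf2 targets rose (mean 0.73 ± 0.18, adjusted p = 0.000152, adjusted p = 0.323 with an estimated correlation), and 19 of 26 measured members were not called and 7 rose, with Gsta3 (4.22 ± 0.69) and Akr7a3 (2.22 ± 0.39) among the largest. Targets of the tumour suppressor p53 rose by less (mean 0.32 ± 0.082, adjusted p = 0.00687, adjusted p = 0.323 with an estimated correlation), and no member of 16 measured was called at 2-fold, with 9 higher and 2 lower at the adjusted p alone. Abcc3 (1.35 ± 0.21) and Ces2 (1.43 ± 0.21), CAR and PXR targets, rose, and the sulfotransferase Sult2a1 fell (-1.53 ± 0.97) with 2 of 4 other probes opposed, while that list was not called (mean -0.13 ± 0.10, adjusted p = 0.776).

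Male-biased liver genes fell under 1-amino-2-methylanthraquinone (mean -0.85 ± 0.18, adjusted p = 0.00101, adjusted p = 0.234 with an estimated correlation), and 10 of 14 measured members were not called and 4 fell, with the male-specific cytochrome Cyp2c11 at -1.79 ± 0.54. Bile acid synthesis and transport fell (mean -0.52 ± 0.074, adjusted p = 0.00303, adjusted p = 0.190 with an estimated correlation), and 13 of 16 measured members were not called and 3 fell, with the racemase Amacr at -1.64 ± 0.16 and Slc27a5 at -1.31 ± 0.10. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, fell (-1.03 ± 0.85), a call that ended without replicate 4 (-0.62, adjusted p = 0.212). Periportal genes fell (mean -0.51 ± 0.072, adjusted p = 0.0366, adjusted p = 0.593 with an estimated correlation), and 15 of 18 measured members were not called and 3 fell: Sds (-2.25 ± 0.62), G6pc1 (-1.55 ± 0.89) and the histidine ammonia-lyase Hal (-1.52 ± 0.52). Hepatocyte secreted proteins fell (mean -0.59 ± 0.14, adjusted p = 2.68e-07, adjusted p = 0.234 with an estimated correlation), and 17 of 20 measured members were not called and 3 fell, with Apoa2 and Fetub (-1.40 ± 0.27) among them and Apoc3 (-1.13 ± 0.15) opposed by 2 of 2 other probes. The fatty acid binding protein Fabp1 (-1.33 ± 0.59) and the lipase inhibitor Angptl4 (-1.08 ± 0.029), PPARalpha targets, fell, while their list was not called (mean -0.10 ± 0.062, adjusted p = 0.522). Lbp, which binds bacterial lipopolysaccharide, rose by 2.0 ± 1.09 without a call for the acute phase response (mean 0.30 ± 0.14, adjusted p = 0.0724). Against the mean of the other 5 compounds that list was called (mean 0.51, adjusted p = 4.15e-05, adjusted p = 0.192 with an estimated correlation), and so was cholesterol synthesis, lower (mean -0.62, adjusted p = 5.02e-05, adjusted p = 0.679 with an estimated correlation). Of the 8 lists called against vehicle, Nrf2 targets, periportal genes and secreted proteins were not called in that contrast. The other 5 lists were, and an estimated correlation ended those calls (adjusted p 0.121 to 0.580). Median centring ended the calls for Nrf2, p53 and aryl hydrocarbon receptor targets, with means below 0 for Nrf2 and p53 targets.

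Monuron, a phenylurea, raised the glutathione transferase Gsta3 and the acyl-CoA synthetase Acsm5 most among the named genes. Gsta3 rose by 5.25 ± 0.063, Gstt3 by 2.25 ± 0.037, Gpx2 by 2.52 ± 0.16, Akr7a3 by 2.5 ± 0.19, Aldh1a1 by 2.60 ± 0.14 and Aldh1a4 by 2.36 ± 0.18. Acsm5 (3.46 ± 0.37), Grin2c (3.30 ± 0.084), the fatty acid carrier Cd36 (2.52 ± 0.11) and Samd7 (2.46 ± 0.22) rose as well. Decreases were in Marveld1 (-2.07 ± 0.21), the cadherin gene Cdh17 (-2.0 ± 0.46), Cyp2c11 (-1.53 ± 0.31), the fatty acid binding protein Fabp5 (-1.43 ± 0.16) and the protease inhibitor Mug1 (-1.35 ± 0.16). Hao2 (-1.33 ± 0.16), the activin subunit Inhba (-1.26 ± 0.23), the NADPH oxidase Nox4 (-1.23 ± 0.25), Aldh1b1 (-1.22 ± 0.13) and Csrp1 (-1.20 ± 0.038) fell too. Of these 20 genes, 19 moved in the same direction against 1,2-dichlorobenzene, which was scanned on the same day, and 7 passed an adjusted p under 0.05 there.

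Monuron changed 161 genes against vehicle, 85 higher and 76 lower, and 103 of them also passed against the other 5 compounds. That contrast called 70 genes, 47 higher and 23 lower. Median centring in place of loess called 47 genes higher and 423 lower against vehicle.

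Cholesterol synthesis rose as a list under monuron (mean 0.81 ± 0.24, adjusted p = 1.10e-10, adjusted p = 0.249 with an estimated correlation), and 12 of 19 measured members were not called and 7 rose. The isomerase Idi1 (1.79 ± 0.38), the synthase Hmgcs1 (1.59 ± 0.51), the oxidase Msmo1 (1.51 ± 0.44) and the squalene epoxidase Sqle (1.40 ± 0.46) had the largest values. Nrf2 targets rose (mean 0.90 ± 0.051, adjusted p = 9.61e-10, adjusted p = 0.190 with an estimated correlation), and 20 of 26 measured members were not called and 6 rose. Aryl hydrocarbon receptor targets rose (mean 0.80 ± 0.053, adjusted p = 0.0226, adjusted p = 0.225 with an estimated correlation), and 5 of 8 measured members were not called and 3 rose: Cyp1a1 (2.77 ± 0.37), Nqo1 (1.60 ± 0.13) and Cyp1a2 (1.54 ± 0.055). Among CAR and PXR targets, which rose as a list (mean 0.44 ± 0.051, adjusted p = 3.89e-05, adjusted p = 0.216 with an estimated correlation), 4 rose, 1 fell and 13 of 18 measured members were not called, with Ugt2b1 at 2.12 ± 0.068, Cyp2c6v1 at 1.29 ± 0.14 and Cyp3a9 at -1.70 ± 0.35. Female-biased liver genes rose (mean 0.62 ± 0.10, adjusted p = 0.00105, adjusted p = 0.216 with an estimated correlation), and 7 of 9 measured members were not called and 2 rose, Ugt2b1 and the prolactin receptor Prlr (1.29 ± 0.18). Targets of p53 rose (mean 0.23 ± 0.046, adjusted p = 0.00150, adjusted p = 0.234 with an estimated correlation), and 15 of 16 measured members were not called and 1 rose, the death receptor gene Fas (1.27 ± 0.12). PPARalpha targets rose slightly (mean 0.14 ± 0.050, adjusted p = 0.0301, adjusted p = 0.627 with an estimated correlation), and no member of 28 measured was called at 2-fold, with 8 higher and 4 lower at the adjusted p alone, a call that ended without replicate 4 (0.11, adjusted p = 0.0607). Oxidative phosphorylation rose slightly too (mean 0.077 ± 0.042, adjusted p = 0.00733, adjusted p = 0.627 with an estimated correlation), and no member of 29 measured was called at 2-fold, with 13 higher and 4 lower at the adjusted p alone. Median centring in place of loess ended the calls for Nrf2, aryl hydrocarbon receptor, CAR and PXR and p53 targets and for female-biased genes, and put the means of CAR and PXR, p53 and PPARalpha targets, female-biased genes and oxidative phosphorylation below 0.

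Of the 6 tested lists of other cell types, 3 were not called under monuron. Lymphocytes (mean -0.20 ± 0.16, adjusted p = 0.0697), with 0 members higher and 6 lower at the adjusted p alone, stellate cells (mean -0.086 ± 0.13, adjusted p = 0.522), with 1 higher and 5 lower, and bile duct cells (mean 0.073 ± 0.10, adjusted p = 0.523) were those. Red blood cell precursor genes rose (mean 0.87 ± 0.14, adjusted p = 0.00910, adjusted p = 0.389 with an estimated correlation), and 2 of 5 measured members were not called and 3 rose: the beta globin Hbb (1.64 ± 0.22), the haem synthesis enzyme Alas2 (1.13 ± 0.10) and the globin chaperone Ahsp (1.05 ± 0.17), which was under 2-fold without replicate 4 (0.97). Kupffer cell and macrophage genes rose (mean 0.32 ± 0.29, adjusted p = 0.0297, adjusted p = 0.684 with an estimated correlation), and 12 of 13 measured members were not called and 1 rose, the scavenger receptor Marco (1.07 ± 0.45), which missed 2-fold without replicate 1 (0.86). The call for the Kupffer list ended without replicate 1 (0.17, adjusted p = 0.198). Liver endothelium genes rose (mean 0.20 ± 0.17, adjusted p = 0.0402, adjusted p = 0.615 with an estimated correlation), and no member of 6 measured was called at 2-fold, with 4 higher and 0 lower at the adjusted p alone, a call that ended without replicate 1 (0.14, adjusted p = 0.118) and without replicate 2 (0.17, adjusted p = 0.0766). Median centring ended the calls for all 3 of these lists and turned the Kupffer and endothelial means negative.

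Periportal genes fell under monuron (mean -0.54 ± 0.15, adjusted p = 0.00352, adjusted p = 0.323 with an estimated correlation), and 13 of 18 measured members were not called and 5 fell, including Sds (-1.69 ± 0.53) and Pck1 (-1.36 ± 0.57). Hepatocyte secreted proteins fell (mean -0.53 ± 0.014, adjusted p = 8.98e-10, adjusted p = 0.190 with an estimated correlation), and 18 of 20 measured members were not called and 2 fell, Ambp (-1.08 ± 0.037) and Apoc3 (-1.06 ± 0.080). Car3 (-1.15 ± 0.20), Oat (-1.14 ± 0.16) and Dhrs7 (-1.99 ± 0.31, other probe opposed) fell too. Against the mean of the other 5 compounds 9 of the 13 called lists kept their call. Aryl hydrocarbon receptor targets, oxidative phosphorylation, periportal genes and secreted proteins did not. Called there and not against vehicle were bile acid synthesis and transport (mean 0.26, adjusted p = 0.00352) and perivenous genes (mean 0.49, adjusted p = 0.000310), which were higher, and bile duct cells (mean -0.27, adjusted p = 0.0131), which were lower. With an estimated correlation the 9 and these calls were lost (adjusted p 0.121 to 0.818). Bile duct genes lay at 1.28 against vehicle under 1-amino-2-methylanthraquinone and from -0.021 to 0.17 elsewhere, which weighs on their call.

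1,2-Dichlorobenzene, which the design names a non-carcinogen, raised the glutathione transferases Gsta3 and Gstp1 and lowered Inmt and Oat most among the named genes. Gsta3 rose by 4.99 ± 0.37, Gstp1 by 4.64 ± 0.39, Ugt2b7 by 4.12 ± 0.19, Akr7a3 by 3.58 ± 0.23 and Nqo1 by 2.39 ± 0.25. Phgdh (2.64 ± 0.21), the prostaglandin and leukotriene reductase Ptgr1 (2.55 ± 0.54), Aldh1a1 (2.48 ± 0.31), Gpx2 (2.40 ± 0.37) and Samd7 (2.38 ± 0.57) also rose. Inmt (-4.69 ± 0.22), Oat (-3.72 ± 0.61), Cyp3a9 (-3.26 ± 0.49), the major urinary protein genes Mup4l3 (-2.25 ± 1.01) and Mup4l4 (-1.91 ± 0.96) and Sez6 (-2.19 ± 0.34) fell. Mme (-2.06 ± 0.093), Slc1a2 (-2.06 ± 0.40), Slc27a5 (-1.65 ± 0.052) and the oestrogen sulfotransferase Sult1e1 (-1.64 ± 0.24) also fell. Cyp1a1 was well above background in the treated channel and not in the vehicle channel, and rose at least 3.17-fold. Against monuron, scanned on the same day, 16 of the 20 genes other than Cyp1a1 kept their direction and 15 passed an adjusted p under 0.05.

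1,2-Dichlorobenzene changed 183 genes against vehicle, 90 higher and 93 lower, and 134 of them also passed against the other 5 compounds. That contrast called 60 genes, 34 higher and 26 lower. Median centring in place of loess called 63 genes higher and 398 lower against vehicle, and 36 and 16 against the other 5 compounds.

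Nrf2 targets rose most as a list under 1,2-dichlorobenzene (mean 1.31 ± 0.22, adjusted p = 3.65e-11, adjusted p = 0.190 with an estimated correlation), and 15 of 26 measured members were not called and 11 rose, among them Abcc3 (1.26 ± 0.17), Me1 (1.47 ± 0.17) and the epoxide hydrolase Ephx1 (1.12 ± 0.28). Cell cycle genes rose (mean 0.49 ± 0.44, adjusted p = 0.00137, adjusted p = 0.641 with an estimated correlation), and 21 of 23 measured members were not called and 2 rose: Mcm6 (1.49 ± 0.53) and Mcm3 (1.42 ± 0.54), which act in replication licensing. Oxidative phosphorylation rose slightly (mean 0.12 ± 0.013, adjusted p = 0.00510, adjusted p = 0.615 with an estimated correlation), and no member of 29 measured was called at 2-fold, with 13 higher and 4 lower at the adjusted p alone. Asns (1.37 ± 0.28) and Fgf21 (1.40 ± 0.62) rose with Phgdh, while the list of ER stress and amino acid response was not called (mean 0.34 ± 0.12, adjusted p = 0.0519). Ugt2b1 rose by 2.36 ± 0.21, and CAR and PXR targets were not called (mean 0.16 ± 0.080, adjusted p = 0.152). Perivenous hepatocyte genes fell (mean -0.70 ± 0.10, adjusted p = 0.00176, adjusted p = 0.216 with an estimated correlation), and 11 of 15 measured members were not called and 4 fell: Oat, Slc1a2, the transporter Slc13a3 (-1.40 ± 0.63) and Cyp1a2 (-1.19 ± 0.59), which missed 2-fold without replicate 2 (-0.99). The median of the list, -0.30, was less than the mean in size. Periportal genes fell (mean -0.45 ± 0.11, adjusted p = 0.00687, adjusted p = 0.375 with an estimated correlation), and 15 of 18 measured members were not called and 3 fell, with Sds at -1.40 ± 0.77 and Aldh1b1 at -1.13 ± 0.18. Male-biased liver genes fell (mean -0.59 ± 0.16, adjusted p = 0.00762, adjusted p = 0.323 with an estimated correlation), and 10 of 14 measured members were not called and 4 fell, with Car3 at -1.65 ± 0.32, Cyp2c11 at -1.3 ± 0.49 and Dhrs7, whose other probe was opposed, at -1.74 ± 0.34. Hepatocyte secreted proteins fell (mean -0.63 ± 0.10, adjusted p = 3.65e-11, adjusted p = 0.190 with an estimated correlation), and 15 of 20 measured members were not called and 5 fell, among them Apoc3 (-1.25 ± 0.28), Fetub (-1.15 ± 0.11), Apoa2 (-1.11 ± 0.21) and Serpina1 (-1.10 ± 0.10).

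Of the 6 tested lists of other cell types, 3 were not called under 1,2-dichlorobenzene. Liver endothelium (mean -0.029 ± 0.11, adjusted p = 0.878), bile duct cells (mean 0.17 ± 0.16, adjusted p = 0.523) and red blood cell precursors (mean -0.061 ± 0.28, adjusted p = 0.557) were those. In the acute phase response, which fell as a list (mean -0.32 ± 0.093, adjusted p = 0.000797, adjusted p = 0.234 with an estimated correlation), 1 rose, 3 fell and 20 of 24 measured members were not called: the transferrin receptor Tfrc was higher (1.13 ± 0.25) and Hp lower (-1.23 ± 0.090). Interferon response genes fell (mean -0.40 ± 0.082, adjusted p = 0.00576, adjusted p = 0.632 with an estimated correlation), and no member of 15 measured was called at 2-fold, with 0 higher and 9 lower at the adjusted p alone. Kupffer cell and macrophage genes fell (mean -0.35 ± 0.20, adjusted p = 0.0174, adjusted p = 0.662 with an estimated correlation), and no member of 13 measured was called at 2-fold, with 0 higher and 8 lower at the adjusted p alone, a call that ended without replicate 1 (-0.25, adjusted p = 0.0724). Genes of stellate cells and fibrosis fell (mean -0.29 ± 0.052, adjusted p = 0.000837, adjusted p = 0.389 with an estimated correlation), and no member of 20 measured was called at 2-fold, with 0 higher and 15 lower at the adjusted p alone. Lymphocyte genes fell (mean -0.21 ± 0.075, adjusted p = 0.0425, adjusted p = 0.646 with an estimated correlation). No member of 12 measured was called at 2-fold, with 0 higher and 7 lower at the adjusted p alone. The list call ended without replicate 1, 3 or 4 (-0.21 to -0.19, adjusted p 0.0541 to 0.0671). Against the mean of the other 5 compounds 8 of the 12 called lists kept their call, and male-biased and periportal genes, oxidative phosphorylation and lymphocytes did not. All 8 were lost with an estimated correlation (adjusted p 0.199 to 0.751). Median centring ended the calls for stellate cells and lymphocytes and turned oxidative phosphorylation negative.

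Tetracycline hydrochloride changed the fewest genes against vehicle. Egr1, an immediate early transcription factor, rose by 1.80 ± 0.66, Prlr by 1.26 ± 0.38, Idi1 by 1.13 ± 0.57 and the sialyltransferase St8sia1 by 1.09 ± 0.32. The immunoglobulin alpha heavy chain Igha (-1.47 ± 0.16), the pseudogene Abcf2-ps2 (-1.16 ± 0.11) and the apolipoprotein Apoe (-1.04 ± 0.15) fell. These 7 were all the genes that met the rule for naming, and all 7 kept their direction against hexachloroethane, scanned on the same day, with 4 past an adjusted p under 0.05. Without replicate 1 the changes of Idi1 (0.93) and Apoe (-0.96) were under 2-fold, and without replicate 3 so was that of St8sia1 (0.99), whose other probe was opposed.

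Tetracycline hydrochloride changed 33 genes against vehicle, 18 higher and 15 lower, and 17 of them also passed against the other 5 compounds. That contrast called 66 genes, 29 higher and 37 lower, and there the vehicle differs too, water for this compound and not for the other 5. Median centring in place of loess called 19 genes higher and 164 lower against vehicle and 40 and 25 against the other 5 compounds, and without background correction the split against vehicle was 8 and 11. The count was 20 without replicate 1 and 56 without replicate 4. Replicate 1 held 4931 spots in blocks shifted against the rest of the array, and with these masked the count was 32.

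Cholesterol synthesis rose as a list under tetracycline hydrochloride (mean 0.33 ± 0.28, adjusted p = 0.000154, adjusted p = 0.598 with an estimated correlation), and 18 of 19 measured members were not called and 1 rose, Idi1. CAR and PXR targets rose slightly (mean 0.16 ± 0.19, adjusted p = 0.0464, adjusted p = 0.604 with an estimated correlation), and 17 of 18 measured members were not called and 1 rose, Ugt2b1 (1.01 ± 0.29), which missed 2-fold without replicate 1 (0.87). The list call ended without replicate 1, 2 or 3 (0.10 to 0.16, adjusted p 0.0544 to 0.140). Hepatocyte secreted proteins fell (mean -0.42 ± 0.051, adjusted p = 4.10e-07, adjusted p = 0.234 with an estimated correlation), and 19 of 20 measured members were not called and 1 fell, Apoc3 (-1.08 ± 0.10), with 2 of 2 other probes opposed. Genes of stellate cells and fibrosis fell (mean -0.17 ± 0.032, adjusted p = 0.0137, adjusted p = 0.604 with an estimated correlation), and no member of 20 measured was called at 2-fold, with 0 higher and 7 lower at the adjusted p alone. Gsta3 rose by 1.54 ± 1.13 without a call for Nrf2 targets (mean 0.17 ± 0.11, adjusted p = 0.0578). None of the 4 lists kept its call against the mean of the other 5 compounds. Called there and not against vehicle were Nrf2 targets (mean -0.68, adjusted p = 1.04e-07), cell cycle (mean -0.44, adjusted p = 0.00143), bile duct cells (mean -0.38, adjusted p = 0.00723), aryl hydrocarbon receptor targets (mean -0.60, adjusted p = 0.0271) and p53 targets (mean -0.16, adjusted p = 0.0404), which were lower, and bile acid synthesis and transport (mean 0.24, adjusted p = 0.0157), which was higher. All 6 were lost with an estimated correlation (adjusted p 0.180 to 0.818). 1-Amino-2-methylanthraquinone weighs on the bile duct call here too. Median centring ended the call for stellate cells and turned cholesterol synthesis and CAR and PXR targets negative.

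**Figure D2:**
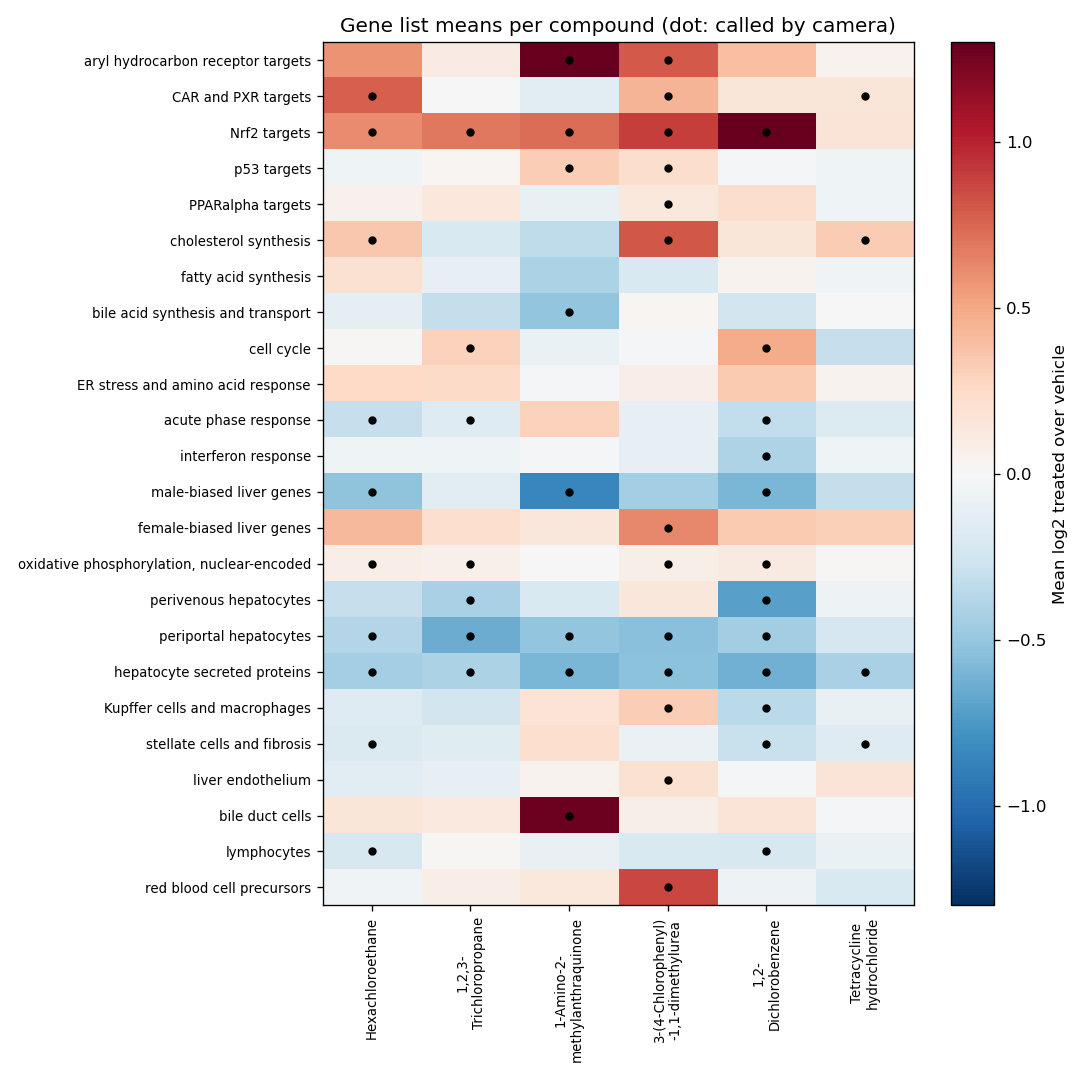
Mean log2 ratio of treated over vehicle (colour, red above 0 and blue below) of each gene list (vertical axis) under each of the 6 compounds (horizontal axis), with a dot where camera called the list. Nrf2 targets under 1,2-dichlorobenzene (1.31), bile duct cells (1.28) and aryl hydrocarbon receptor targets (1.32) under 1-amino-2-methylanthraquinone had the highest means.

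Gsta3 was called higher under all 6 compounds. Acsm5, Aldh1a1, Gpx2, Gstt3, Nqo1 and Ugt2b1, which include enzymes that conjugate or reduce reactive compounds, were called higher under 5. Apoc3, Car3, Dhrs7, Oat, Sds and the phosphatase Dusp1 were called lower under 5. Apoc3 (other probes -0.15 over all arrays) and Dhrs7 (other probe opposed under some) rest on 1 probe each. Counted over all genes, 164 were higher under 1 compound and 1 under all 6, while 124 were lower under 1 compound, 9 under 5 and 0 under all 6 in limma. With both directions added up, 1,2-dichlorobenzene had the largest overlaps. It shared 37 genes higher and 44 lower with 1-amino-2-methylanthraquinone, with 1.14 and 0.809 met by chance, and 38 higher and 41 lower with monuron, with 0.666 and 0.615 by chance. Of genes called higher, 1-amino-2-methylanthraquinone and monuron shared the most, 40. A shared vehicle pool, or a dye effect alike on all arrays, would add to these overlaps, and Abcf2-ps2 lay between -1.16 and -0.92 under all 6 compounds. Among the gene lists, 54 of 144 tests were called with the preset correlation, 27 higher and 27 lower, and 0 with an estimated correlation, while the list of hepatocyte secreted proteins was lower under all 6 compounds. With median centring 40 tests were called, 4 higher and 36 lower, 25 of them shared. Fatty acid synthesis was not called under any compound, with list means from -0.41 ± 0.56 under 1-amino-2-methylanthraquinone (adjusted p = 0.266) to 0.20 ± 0.21 under hexachloroethane. Nor was ER stress and amino acid response, at 0.34 ± 0.12 under 1,2-dichlorobenzene and 0.26 ± 0.31 under hexachloroethane (both adjusted p = 0.0519). Neutrophil genes (4 measured) and pancreatic acinar genes (2 measured) were too few to test.

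**Figure D3:**
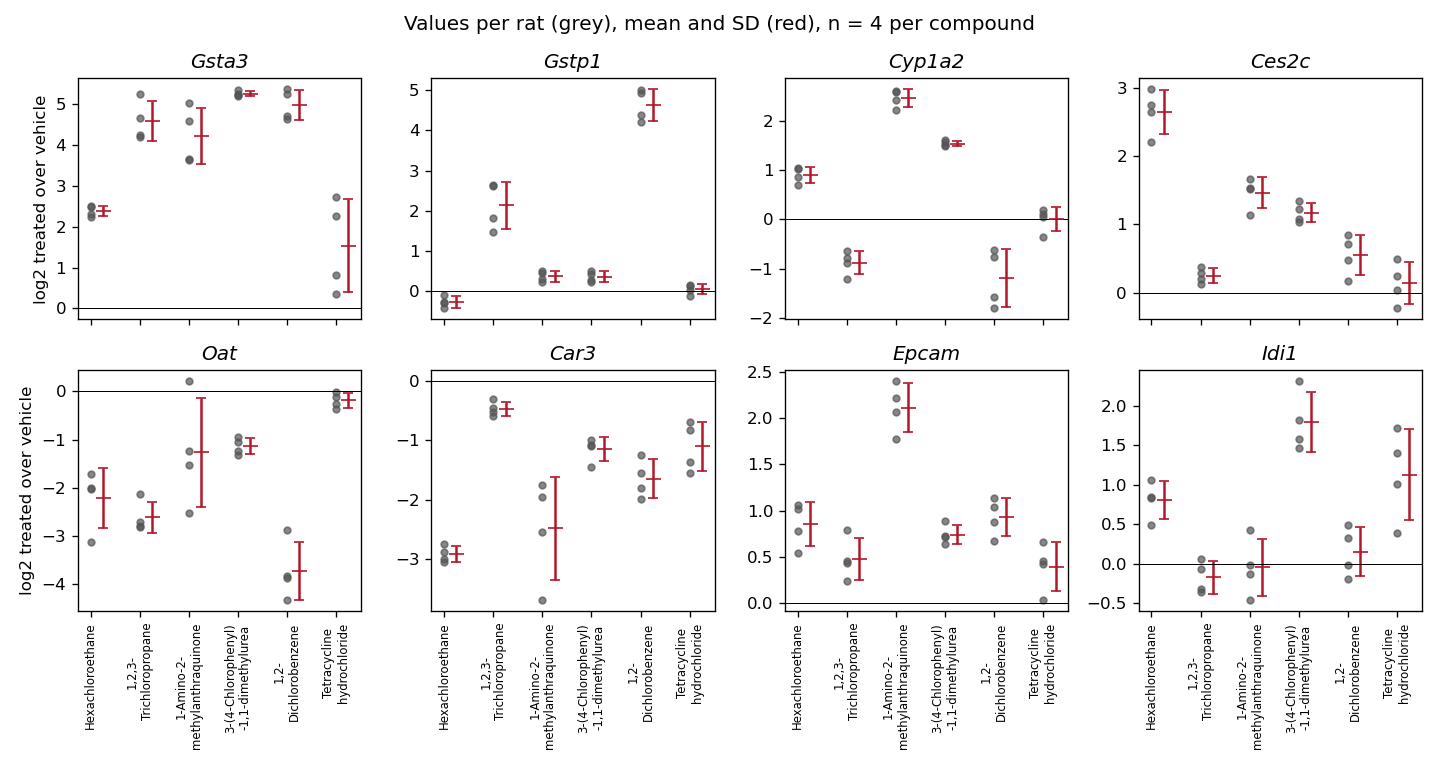
Log2 ratio of treated over vehicle (vertical axis) of 8 genes in each of the 4 rats per compound (points) with the mean. Gsta3 lay above 0 on average under all 6 compounds, from 1.54 under tetracycline hydrochloride to 5.25 under monuron.

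The series sets 4 carcinogens against 2 non-carcinogens, and at the level of single genes no difference was called. The replicate in this comparison is the compound, 4 against 2. With compound as a random block in limma, 0 genes were called (smallest adjusted p = 0.9999) and 191 had an unadjusted p under 0.05, where 575 are met by chance. The compound means taken as 6 samples called 0 genes (136 unadjusted), and a fit without the block called 2 (1696 unadjusted), Spdye4c (-1.20) and a transcript without a symbol. Cyp1a2 was 1.60 log2 higher on average under the carcinogens (SE 0.53, unadjusted p = 0.00568), with compound means from -1.19 under 1,2-dichlorobenzene to 2.46 under 1-amino-2-methylanthraquinone and -0.88 under the carcinogen 1,2,3-trichloropropane. The p53 target Phlda3 was 0.60 higher (SE 0.21) and the mitochondrial superoxide dismutase Sod2 0.27 higher (SE 0.068). These genes were picked after their values were seen. In simulated log ratios, with the spread of each gene and an effect of each compound of its own added, this test found 0 of 65 genes with a 1.5-fold class difference, 26 of 77 with a 2-fold difference (33.8%) and 55 of 58 with a 4-fold difference. The simulated compound effects were small beside the spread of the compound means of a gene such as Cyp1a2. For such genes these shares are too high.

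With scan day added after the data were examined, 15 genes were called, 8 higher and 7 lower under carcinogens. Ces2 (1.35), Ces2c (1.57), Cyp1a2 (1.82), Cyp3a23-3a1 (1.23) and Grin2c (2.34) were higher, and Gstp1 (-2.30) and Mt1 (-2.09) lower. That estimate rests on 4 compounds, hexachloroethane against tetracycline hydrochloride on day 1 and monuron against 1,2-dichlorobenzene on day 4. With 1 compound per class and day, the 15 calls cannot be told apart from compound differences. Outside it, the carcinogen 1,2,3-trichloropropane had the opposite sign for Gstp1 (2.14), Mt1 (1.99) and Cyp1a2 (-0.88), not for Ces2, Ces2c and Grin2c.

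None of the gene lists separated the classes in an exact permutation test of the 15 ways to part the 6 compounds into 4 and 2, 2-sided. The smallest exact p this design allows is 0.0667. The smallest observed was 0.133 for the interferon response, 0.17 log2 higher under carcinogens. Targets of the aryl hydrocarbon receptor were 0.49 higher (exact p = 0.267), targets of p53 0.17 higher (exact p = 0.2) and Nrf2 targets differed by -0.0061 (exact p = 1). The lists were also compared within scan days, 4 rats of 1 carcinogen against 4 of 1 non-carcinogen, which was chosen after the data were examined. On day 1 the vehicles differed too, corn oil against water. Several of the 24 lists reached the smallest exact p of 0.0286. After adjustment over the 24 lists none passed (exact test, adjusted p = 0.114 on day 1 and 0.0571 on day 4). The smallest exact p was reached on both days by 5 lists. Aryl hydrocarbon receptor targets were 0.54 higher under hexachloroethane and 0.41 higher under monuron, and CAR and PXR targets were higher on both days too (0.61 and 0.28). The median differences of the aryl hydrocarbon receptor targets were smaller, 0.059 and 0.20. The other 3 lists went opposite ways: Nrf2 targets (0.44 and -0.41), acute phase response (-0.13 and 0.21) and perivenous hepatocytes (-0.23 and 0.86). The median differences of the perivenous genes were -0.064 and 0.34. Targets of p53 differed by 0.0048 on day 1 (exact p = 0.943) and 0.25 on day 4 (exact p = 0.0286).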

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

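Tests chosen after the result was seen were those of differences between compounds in the secreted protein list, of a dye effect of its transcripts, of a lower share of hepatocytes and of a dye effect for bile duct genes, and of single rats for the genes that part hexachloroethane from 1,2,3-trichloropropane.

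In groups of 4 rats, 14 of 185 sets of values held a rat far from the other 3 by Dixon's test (7.57%), where chance gives about 1 in 20. The mean correlation with the other rats of its compound was 0.554 for hexachloroethane replicate 1 (0.706 to 0.711 in the others) and 0.444 for tetracycline hydrochloride replicate 4 (0.597 to 0.606). The correlation between copies of a probe was 0.823 for monuron replicate 1 (0.934 to 0.948) and 0.729 for tetracycline hydrochloride replicate 1 (0.891 to 0.903). Among gene lists, Nrf2 targets had a mean of 0.67 in hexachloroethane replicate 4 (0.58 to 0.59) and 0.77 in 1,2,3-trichloropropane replicate 1 (0.65 to 0.67). Male-biased genes had -0.65 in hexachloroethane replicate 4 (-0.49 to -0.46), aryl hydrocarbon receptor targets 1.12 in 1-amino-2-methylanthraquinone replicate 2 (1.38 to 1.42) and PPARalpha targets 0.21 in monuron replicate 4 (0.11 in the others). Among genes, Grin2c was 3.02 in hexachloroethane replicate 2 (4.01 to 4.15), Oat -2.13 in 1,2,3-trichloropropane replicate 1 (-2.81 to -2.70) and Slc27a5 -1.57 in 1,2-dichlorobenzene replicate 2 (-1.68 to -1.67). In 1-amino-2-methylanthraquinone replicate 1, Aldh1a1 was 2.82 (2.31 to 2.36) and Hao2 -2.53 (-1.66 to -1.56).

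Hepatocyte secreted proteins were lower against vehicle under all 6 compounds. A bend at bright probes would keep the list among random lists matched on brightness. In 6 compounds its median lay below their 2.5th percentile. The match was not tested at the brightest probes, where a bend stays open. A dye effect of the chosen probe alone would leave the other probes of the same genes at 0, and they averaged -0.32 over 11 members (SE 0.072). The size of the fall differed between compounds (permutation p = 0.00343, 100000 resamples). A dye effect of these genes alike on all arrays does not account for that. With no dyes swapped, the fall all compounds share (-0.41 at the smallest) cannot be told apart from such a dye effect. No biological explanation was tested.

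Bile duct genes were higher under 1-amino-2-methylanthraquinone. A lower share of hepatocytes would raise the markers of all other cell types alike, and the list lay 1.19 log2 above the mean of 4 other cell type lists (SD 0.20, n = 4, 0.90 to 1.32 in single rats). A dye effect alike on all arrays would cancel against the other 5 compounds, where the list was called (adjusted p = 1.04e-07, adjusted p = 0.192 with an estimated correlation), and the list stayed called in 4 of 4 fits without 1 rat. A hypothesis open to further work is that the compound raised the number of bile duct cells, or the activity of these genes in cells already present, and these 2 could not be told apart by the tests run.

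Noct, Tsku, Zfp354a, Tat and Insig1 were higher under hexachloroethane than under 1,2,3-trichloropropane. Noct has a daily rhythm, and a difference in the time of collection would move the clock genes. Their score differed by -0.086 log2 (exact p = 0.457, 70 splits, 2-sided), less than the 0.5 set beforehand. Over the compounds it ran from -0.41 (1-amino-2-methylanthraquinone) to 0.58 (monuron), so collection time stays open in other contrasts. Noct, Tsku, Zfp354a and Insig1 were called in 8 of 8 fits without 1 rat, which argues against a single rat. Tat was called in 5 of 8 in limma, with a difference above 1 log2 in all 8. Its call was lost without hexachloroethane replicate 1 and without 1,2,3-trichloropropane replicate 3 or 4 (adjusted p 0.0600 to 0.0686). A single rat cannot be told apart here from a p near the threshold. Dose, slide and scan day differ with the compound, as the vehicle pool and the time of collection may. All of these stay open, and no biological explanation was tested.

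The groups were also compared with other groupings of the same arrays. For each compound against the mean of the other 5, 1 of 100 label sets, the real one, called as many genes, so chance in the grouping of the arrays is excluded as the source of the counts, while a difference between vehicle pools or slides, which the 4 arrays of a compound share, is not. The real counts and the highest of the other sets were 73 and 36 for hexachloroethane, 47 and 30 for 1,2,3-trichloropropane, 149 and 71 for 1-amino-2-methylanthraquinone, 70 and 62 for monuron, 60 and 16 for 1,2-dichlorobenzene and 66 and 32 for tetracycline hydrochloride. Between hexachloroethane and 1,2,3-trichloropropane 1 of 35 splits, the real one, called as many genes (160, highest other 13), which argues against chance there with the same limits. For the classes, the real split of the 6 compounds called 0 genes in limma and the highest other 14, with 1,2,3-trichloropropane and 1,2-dichlorobenzene apart from the rest, and 15 splits are too few for a share under 0.05. At an unadjusted p under 0.05 the real split gave 191 genes and the others 129 to 2010, which points to a structure of the samples.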

How the results depend on the processing

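Alternatives chosen after the data were examined were scan day as a block and within scan day for the classes, masking of shifted blocks of spots, and lists against the mean of the other 5 compounds.

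No named gene reversed under any setting in which it could be tested, and the strict filter on dim probes left 209 of 221 named values against vehicle. Of 221 named values against vehicle, 33 were no longer called with the mean of all kept probes, 38 with median centring in place of loess, 28 without background correction, 19 with the scanner's log ratio, 19 with the series table, 6 with only the 4 arrays of a compound and 1 with shifted blocks masked, and 36 of 884 with 1 rat left out. All 10 genes named for hexachloroethane against 1,2,3-trichloropropane kept their call in every setting run, except that Grin2c could not be tested with the strict filter. Of 54 called lists, 20 were lost and 9 reversed with median centring, 24 and 6 against the mean of the other 5 compounds, 10 of 53 were lost with a strict filter on dim probes, which left red blood cell precursors under monuron with too few members to test, 5 with the scanner's log ratio, 5 with the series table, 4 without background correction and 17 of 216 with 1 rat left out. Median centring moved the median of all genes from between -0.023 and -0.0097 to -0.33 for hexachloroethane, -0.27 for 1,2,3-trichloropropane, -0.34 for 1-amino-2-methylanthraquinone, -0.26 for monuron, -0.21 for 1,2-dichlorobenzene and -0.23 for tetracycline hydrochloride, log2. A block of replicate numbers changed no named call, and after compound means were taken out same-numbered replicates of different compounds had a median r of 0.037 over 60 pairs (-0.26 to 0.39). Signal over background limits which genes could be tested.

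In the order hexachloroethane, then 1,2,3-trichloropropane, then 1-amino-2-methylanthraquinone, monuron, 1,2-dichlorobenzene and tetracycline hydrochloride, the counts that moved were as follows; the cause was not tested. The scanner's log ratio called 293, 284, 548, 306, 349 and 99 genes against vehicle, 187, 107, 367, 128, 140 and 175 against the other 5, and 383 between the chlorinated alkanes. The series table called 296, 277, 535, 297, 343 and 111 against vehicle, 182, 111, 364, 127, 131 and 169 against the other 5, and 388 between the chlorinated alkanes. Median centring called 649, 441, 1082, 470, 461 and 183 against vehicle. Without background correction the counts were 146 for 1-amino-2-methylanthraquinone, 118 for 1,2-dichlorobenzene and 19 for tetracycline hydrochloride against vehicle, and 30 for 1,2,3-trichloropropane, 77 for 1-amino-2-methylanthraquinone, 46 for monuron and 36 for 1,2-dichlorobenzene against the other 5. Because these alternatives drop part of the limit, more genes passed with no fold limit, 4991, 5252, 6755, 5295, 5950 and 4301 against vehicle, 3259, 3515, 5562, 2583, 3573 and 3771 against the other 5 and 4020 between the chlorinated alkanes, and with a 1.5-fold limit, 398, 350, 853, 483, 675 and 176, 243, 214, 587, 203, 265 and 271, and 533.

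Without 1 rat the counts against vehicle ran from 91 to 121, 90 to 129, 228 to 299, 145 to 175, 165 to 235 and 20 to 56, those against the other 5 from 67 to 87, 35 to 57, 118 to 202, 60 to 67, 47 to 85 and 62 to 76, and between the chlorinated alkanes from 137 to 183. Between the classes 0 genes were called in limma in most settings, 2 without the compound block and 3 without tetracycline hydrochloride. With scan day as a block 15 were called, and within days 1 and 4, 93 and 112. Within days and without tetracycline hydrochloride 1 compound stood for a class, so class and compound cannot be told apart.

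With median centring camera's direction for these lists, relative to all other genes, reversed: cholesterol synthesis under hexachloroethane (-0.35) and tetracycline hydrochloride (-0.17), oxidative phosphorylation under hexachloroethane (-0.71), 1,2,3-trichloropropane (-0.64), monuron (-0.62) and 1,2-dichlorobenzene (-0.47), PPARalpha targets (-0.42) and liver endothelium (-0.26) under monuron, and CAR and PXR targets under tetracycline hydrochloride (-0.33). Against the mean of the other 5 compounds these did: periportal genes (0.092) and secreted proteins (0.070) under hexachloroethane, secreted proteins (0.12) and Nrf2 targets (-0.054) under 1,2,3-trichloropropane, and secreted proteins (0.10) and CAR and PXR targets (-0.088) under tetracycline hydrochloride. Other list means crossed 0 without a change of camera's direction: with median centring Nrf2 targets under hexachloroethane (-0.080) and 1-amino-2-methylanthraquinone (-0.024), p53 targets under the latter (-0.20) and monuron (-0.16), and CAR and PXR targets (-0.18), female-biased genes (-0.027) and Kupffer genes (-0.18) under monuron, and against the other 5 compounds Nrf2 targets under hexachloroethane (-0.15) and 1-amino-2-methylanthraquinone (-0.0060) and periportal genes under 1,2-dichlorobenzene (0.0078). The cause was not tested.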

Other observations

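The genes in this part were chosen after their values were seen, and the test of a list between monuron and 1,2-dichlorobenzene was chosen after the data were examined.

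Across the compounds, several liver enzymes and regulators moved under 3 or 4 compounds. Cd36, which carries fatty acids into cells, was called higher under 4 compounds, from 1.14 under 1,2-dichlorobenzene to 2.52 under monuron. The flavin monooxygenase Fmo5 was called higher under 4 as well, with 2.04 under monuron and -0.62 under hexachloroethane, where it was not called higher. The kinase gene Sgk1 was called lower under 4 compounds and lay at -1.51 under 1,2-dichlorobenzene. Ppp1r3c, which encodes a glycogen-targeting subunit of a phosphatase, was called lower under 4, with -1.57 under 1,2,3-trichloropropane. The metallothionein gene Mt1 was called higher under 3 compounds, with 2.11 under 1,2-dichlorobenzene, 1.99 under 1,2,3-trichloropropane and 1.01 under 1-amino-2-methylanthraquinone.

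In blocks of spots shifted by over 0.1 log2 against the rest of the array lay 4931 spots of tetracycline hydrochloride replicate 1 and 636 of monuron replicate 1.

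Red blood cell precursor genes, called higher under monuron, had means of 0.87 ± 0.14 there, -0.061 ± 0.28 under 1,2-dichlorobenzene, which was scanned on the same day, and -0.20 ± 0.23 under tetracycline hydrochloride. Their difference between monuron and 1,2-dichlorobenzene was 0.93 (adjusted p = 0.000247, adjusted p = 0.201 with an estimated correlation).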
